A study of Danio rerio with 48 samples.

How the data were processed

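Messenger RNA of 48 whole zebrafish (Danio rerio) embryos of the RIKEN WT strain was measured, 1 library per embryo, at 24, 36 and 48 hours post fertilisation (hpf). Per the labels, each embryo was homozygous wild type (noc2l +/+) or homozygous mutant (noc2l -/-) and all came from 1 family carrying 1 allele, whose lesion is not given in the sources used here. Libraries were made by Lasy-Seq, which indexes each RNA at reverse transcription, pools the samples early and sequences mainly the 3' ends of polyadenylated transcripts, per the labels' protocols. Counts therefore do not scale with transcript length, and the method sees little of a gene beyond its 3' end.

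The submitters' processing notes name fastp 0.21.0, BWA 0.7.17-r1188, Salmon (version not given in the sources used here) and the genome build GRCz11. The order of these steps, the gene annotation and the way transcripts were summed to genes are likewise not given in the sources used here. The deposited table holds expected counts per gene symbol, not normalised, in 31658 entries for the 48 libraries, of which 3197 hold no count in any library. All but 2 values were whole, both exceptions lying in mitochondrial entries, and expected counts were rounded to whole numbers before testing. A table of sample descriptions was not used here. Reads that fit several near-identical genes can be divided between them by such counting, so values of single members of the lens crystallin family are uncertain. Handling of strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart.

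Total counts ran from 797752 to 11016313 per library, with a median of 5.99 in units of 1000000 counts, and 3 libraries lay under the limit of 2.0 in these units that marks 1/3 of the median. These were wild-type embryo 4 and mutant embryo 8 at 24 hpf and wild-type embryo 9 at 48 hpf. In no pair of libraries of the same group did counts agree within sampling noise (lowest chi-square per degree of freedom 5.26), so every library was counted as a separate embryo.

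Genes were kept by edgeR's filterByExpr (minimum count 10) on the 6 groups, which left 16431 genes holding 99.8% of all counts. TMM factors, negative binomial dispersions and robust quasi-likelihood fits were obtained with edgeR 4.0.16 in R 4.3.3, with 1 mean per group over all 48 libraries; the common biological coefficient of variation was 31.1%. Contrasts gave the genotype effect at each age, its difference between ages, and the change with age within each genotype. Adjusted p-values are from edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05 unless another test is named. Fold changes are given as log2 values with their standard error (SE), derived from the F statistic, and positive values mean higher in mutants or at the later age. Levels are CPM, counts scaled to a library total of 1000000, with TMM scaling, as mean ± SD over embryos. P-values concern embryos of 1 family. Those of edgeR rest on 1 spread per gene shared by all 6 groups, not on that of the groups compared. The lowest correlation between libraries of a group was 0.825 in wild types and 0.847 in mutants at 24 hpf. It was 0.92 and 0.933 at 36 hpf, and 0.882 and 0.911 at 48 hpf.

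The 40 gene lists were fixed in advance and tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The lists covered genes of stress-induced growth arrest and cell death, ribosome biogenesis and other core processes, stress responses, and markers of the cell types and organs of the embryo. A developmental age score was computed for every embryo as the mean log2 CPM of the 200 genes rising most minus that of the 200 falling most in wild types from 24 to 48 hpf, leaving out genes on the chromosome of noc2l. For wild types the genes were chosen anew without the embryo scored. Scores were also expressed as a wild-type-equivalent age by linear interpolation between wild-type group means, and genotypes were compared by exact two-sided permutation tests. Fisher's exact tests were run in R. The remaining exact tests enumerated all rearrangements in Python, with ranks and p-value adjustment from scipy.

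Chromosomes were taken from the RefSeq table of another assembly, GRCz12tu, by gene symbol, and used only to say which genes lie with noc2l; 13745 of the 16431 tested genes (83.7%) were placed.

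Named genes follow a rule: noc2l; a panel of mdm2, cdkn1a, ccng1, baxa and bbc3, of which 1 further member is not reported here; the 6 largest called rises and falls per genotype comparison with a mean of at least 10 CPM in the higher group and a gene symbol that is not a clone name; the 3 members of smallest p of lists that passed the set test or held at least 5 called genes; and the 4 largest called changes each way for the other comparisons. Tests, lists, this rule and most alternatives were chosen before the data were examined. The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma voom with quality weights, no filter and a stricter filter (minimum count 30), only the libraries compared, no shallow libraries, a replicate block, thinning to equal depth, 6 embryos per group, and omission of the noc2l chromosome. After the data were seen 3 more were added: leaving out wild-type embryo 4 or mutant embryo 5 at 24 hpf, and the age score as a covariate of the genotype comparisons.

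The procedure was tested on simulated data with the real means, dispersions and library sizes and 200 changed genes, of which 66, 67 and 64 of the 3 sizes below were among the 16089 genes run. In the comparison of genotypes at 48 hpf, 21.2% of genes changed by 0.5 (log2), 55.2% of those changed by 1 and 82.8% of those changed by 2 were recovered. At 24 hpf the shares were 13.6%, 49.3% and 78.1%, and at 36 hpf 22.7%, 59.7% and 90.6%. These shares come from 1 random draw; an earlier draw with another seed, replaced for a reason unrelated to its outcome, gave lower recovery of the largest changes at all 3 ages. Among unchanged genes 3, 2 and 4 were called at 24, 36 and 48 hpf, and no interaction was called where none was simulated. The list shifted by 0.5 was recovered by camera at each age with no other list called. Genes were simulated independently of one another, so this run could not show false list calls that come from correlated genes. Mutants simulated midway between wild types of 36 and 48 hpf were placed at 42 hpf.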

Results

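The data comprised single-embryo transcript counts for noc2l +/+ and noc2l -/- zebrafish at 24 hpf (6 wild types and 9 mutants), 36 hpf (8 and 9) and 48 hpf (9 and 7). Noc2l is a nucleolar protein known from other work for a role in ribosome biogenesis. Median totals per group, in units of 1000000 counts, lay between 3.52 in wild types at 24 hpf and 7.01 in mutants at 48 hpf. Total counts, genes detected and the share of the 10 most abundant genes did not differ past the threshold between genotypes at any age (exact permutation tests, adjusted p 0.207 or more over 12 tests). Mitochondrially encoded transcripts made up 4.21% ± 0.238 of counts in mutants (n = 9) against 4.76% ± 0.406 in wild types (n = 8) at 36 hpf (exact permutation test, p = 0.00387, adjusted p = 0.0464).

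The transcript of noc2l was lower in mutants at every age. Its mean level at 24 hpf was 20.1 ± 9.49 CPM in wild types (n = 6) and 5.74 ± 4.15 CPM in mutants (n = 9). At 36 hpf it was 15.5 ± 6.20 CPM (n = 8) against 5.42 ± 2.52 CPM (n = 9), and at 48 hpf 13.5 ± 6.09 CPM (n = 9) against 4.23 ± 1.58 CPM (n = 7). The log2 differences were -1.93 (SE 0.34), -1.52 (SE 0.30) and -1.72 (SE 0.34), with edgeR adjusted p of 0.00108, 0.00242 and 0.000687. Genotypes overlapped at every age. At 24 hpf mutant embryo 5 read 16.2 CPM and the shallow wild-type embryo 4 read 6.54 CPM from 6 counts. The lowest wild type and highest mutant were 6.70 and 10.6 CPM at 36 hpf and 5.71 and 6.99 CPM at 48 hpf. Since the lesion is not known here, a 3' tag need not report on it, and these levels check the labels only in part.

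**Figure D1:**
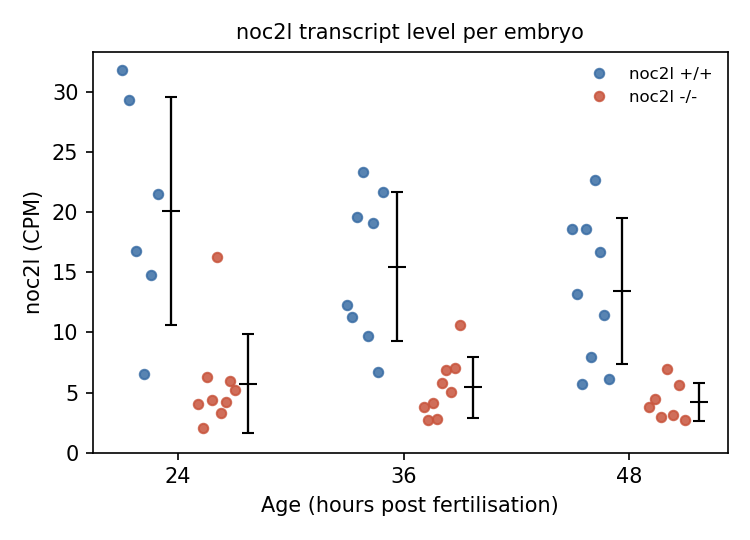
Level of noc2l in CPM (vertical axis) for each embryo (points) at 24, 36 and 48 hours post fertilisation, wild types in blue and mutants in red, with the group mean and SD in black. Mutant means lay at 5.74, 5.42 and 4.23 CPM against 20.1, 15.5 and 13.5 CPM in wild types.

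The first comparison asked how loss of noc2l changed transcripts at 24 hpf. Genes of stress-induced growth arrest and cell death were among those that rose: rps27l, a ribosomal protein S27-like gene, by 1.88 (SE 0.31), ccng1, cyclin G1, by 1.31 (SE 0.21), and mdm2, a ubiquitin ligase, by 1.04 (SE 0.16), with edgeR adjusted p of 0.00108, 0.00108 and 6.56e-05. Also higher were SH3TC1 (1.41), casp8, an initiator caspase (1.29), and isg20, an exonuclease (1.09). The only named gene other than noc2l that fell was pdia6, a protein disulphide isomerase of the endoplasmic reticulum, at -0.68 (SE 0.16), and its call was lost in 10 of the alternatives run. Of the panel, baxa (0.61), bbc3 (1.16) and cdkn1a (1.66) did not pass, with edgeR adjusted p of 0.208, 0.318 and 0.805. In all, 20 of 16431 genes were called, 18 higher and 2 lower.

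Of 29 tested genes of the arrest and cell death list, 4 were higher at 24 hpf and none lower (11 and 0 adjusted over the list alone), with a median of 0.47. The camera test gave an adjusted p of 1.83e-08, and adjusted p = 0.016 with an estimated correlation. Ribosome biogenesis factors, the proteins that assemble ribosomal subunits, had a median of 0.25 over 124 members, with no member called and 6 higher adjusted over the list alone (camera adjusted p = 1.55e-11, adjusted p = 0.363 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.24 with no member of 77 called and 52 higher adjusted over the list alone (camera adjusted p = 6.54e-22, adjusted p = 0.96 with an estimated correlation); examples are rpl11 (0.40), rpl19 (0.32) and rps26 (0.35). Lower on the preset correlation were cell cycle and DNA replication genes (median -0.08), skeletal muscle genes (median -0.09) and lens crystallins (median -0.17), with camera adjusted p of 0.00331, 2.82e-05 and 0.038, and adjusted p = 0.96 with an estimated correlation for each. No member of these 3 lists was called at 24 hpf: among them ncapd2, rrm2 and pole read -0.38, -0.28 and -0.69, myhz2, sgcg and pvalb1 -0.80, -0.58 and -0.57, and crygn1, crygm2d18 and crygm2f 4.49, -0.86 and -2.49, the crystallins near the floor of detection. Embryos at 24 hpf were uneven in developmental age, as scored below, and these list tests were not adjusted for it. Embryos were also divided at random by permuting genotype within every age at once, in 100 divisions with the real one included. At 24 hpf 6 of these gave at least 20 genes. Only the real one called any gene that was higher at 36 hpf, an outcome that the shared fit favours. With limma voom 5 genes were called, with only the 24 hpf libraries 8, and with DESeq2 46. With only the 24 hpf libraries ccng1 read 1.29 and rps27l 1.86 (edgeR adjusted p = 0.647 and 0.646), and casp8 lost its call in 6 alternatives. With limma voom rps27l, SH3TC1 and isg20 did not pass (limma adjusted p of 0.0587, 0.095 and 0.0767).

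**Figure D2:**
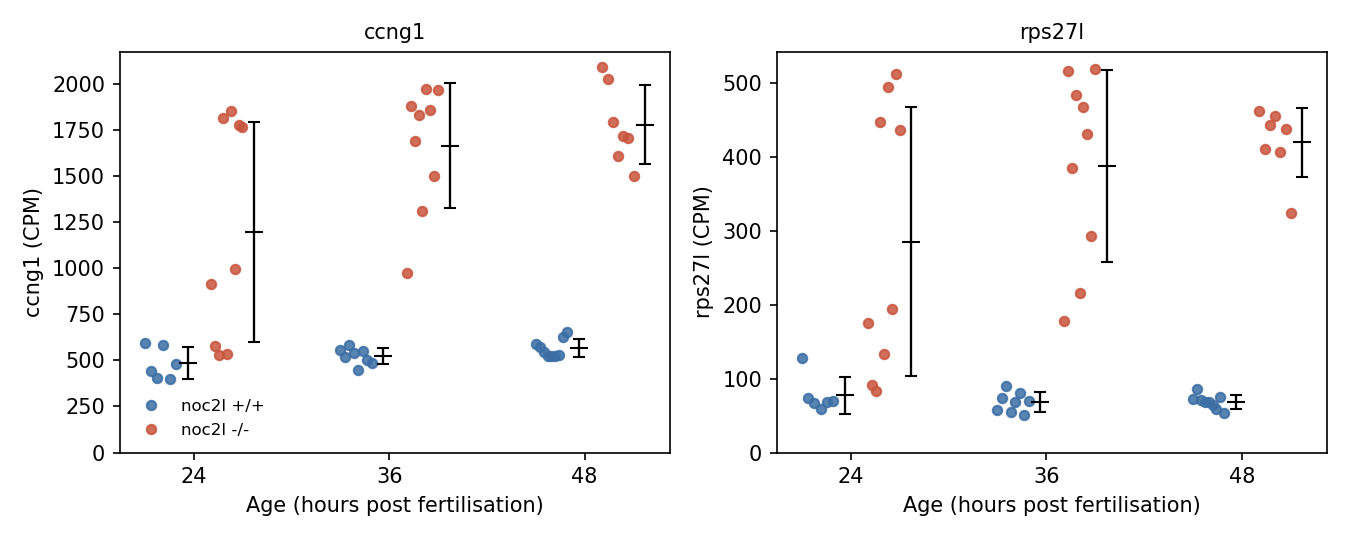
Levels of ccng1 (left) and rps27l (right) in CPM for each embryo (points) by age in hours post fertilisation, wild types in blue and mutants in red, with the group mean and SD in black. At 24 hpf the 9 mutants spread from 529 to 1855 CPM for ccng1.

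At 36 hpf arrest and cell death genes and ribosome assembly genes were higher in mutants. The largest rises were rps27l at 2.51 (SE 0.28) and phlda3, an inhibitor of Akt, at 2.45 (SE 0.37), with edgeR adjusted p of 1.31e-07 and 3.36e-05. Next came bmb (1.82), capn3a, a calpain protease (1.71), and ccng1 (1.67), while mdm2 rose by 1.65 and baxa, a cell death effector, by 0.67. Transcripts of cdkn1a (1.03) and bbc3 (0.80) did not pass, with edgeR adjusted p of 0.938 and 0.369. The largest falls were a mitochondrial transcript listed without a gene symbol (-1.28), acta1a, a skeletal muscle actin (-0.90), rpl22l1 (-0.83), alas2, the first enzyme of haem synthesis in red cells (-0.82), slc25a4, a mitochondrial ADP/ATP carrier (-0.72), and ppdpfb (-0.66), the last a gene on the chromosome of noc2l. Altogether 116 genes were called, 101 higher and 15 lower.

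Of 124 ribosome biogenesis factors 21 were higher at 36 hpf and none lower (68 and 0 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 1.91e-49, adjusted p = 8.13e-05 with an estimated correlation). Examples were noc3l (1.01, SE 0.17), dkc1, the pseudouridine synthase of box H/ACA particles (0.65, SE 0.12), npm1a, nucleophosmin (0.56, SE 0.12), and gar1 (0.54, SE 0.12). At 24 hpf these read 0.37, 0.41, 0.41 and 0.43, none called. Among 28 RNA polymerase I and III genes 5 were higher (10 adjusted over the list alone), including gtf3aa (1.31), rrn3 (0.76) and polr1d (0.65), with a median of 0.27 (camera adjusted p = 3.97e-09, adjusted p = 8.13e-05 with an estimated correlation). At 24 hpf this list did not pass (median 0.19, camera adjusted p = 0.26). The arrest and cell death list had 8 members higher and none lower (10 and 0 adjusted over the list alone), a median of 0.27 and a camera adjusted p of 3.49e-15 (adjusted p = 8.13e-05 with an estimated correlation).

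Cytosolic ribosomal proteins did not pass at 36 hpf (median -0.01, camera adjusted p = 0.817), nor did lens crystallins (median -0.23, camera adjusted p = 0.0522). Other lists moved less, and most of their calls rested on the preset correlation. Primitive erythroid genes had a median of -0.26, with alas2 the 1 called member and 6 lower adjusted over the list alone (camera adjusted p = 3.09e-06, adjusted p = 0.088 with an estimated correlation); slc4a1a read -0.44 and creg1 -0.68. Yolk syncytial and lipoprotein genes had a median of -0.18 and no called member (camera adjusted p = 3.09e-06, adjusted p = 0.088 with an estimated correlation). Translation factors and tRNA synthetases had a median of 0.14 (camera adjusted p = 9.29e-06, adjusted p = 0.139 with an estimated correlation). Oligodendrocyte and glial genes had a median of -0.14 with no called member (camera adjusted p = 0.00833, adjusted p = 0.0422 with an estimated correlation). Lower on the preset correlation alone were mitochondrially encoded transcripts (median -0.11), cell cycle genes (-0.12), differentiated neurons (-0.15), liver (-0.13), fin fold and epidermis (-0.10), skeletal muscle (-0.04), glycolysis (-0.06) and neural progenitors (-0.07), and higher was mRNA splicing (0.06). With an estimated correlation the camera adjusted p of these were 0.273, 0.418, 0.234, 0.168, 0.306, 0.694, 0.418, 0.551 and 0.503. With the 6 lowest-numbered embryos of each group 64 genes were called, and with limma voom 176. Among named genes capn3a lost its call in 6 alternatives, the mitochondrial transcript without a symbol in 4, and slc25a4 and baxa in 2 each. With 6 embryos per group bmb, acta1a, rpl22l1 and rrn3 also lost theirs (edgeR adjusted p of 0.0548, 0.0676, 0.25 and 0.0939).

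At 48 hpf 362 genes were called, 245 higher and 117 lower, more than at either earlier age. Counts of calls do not show that effects were larger, which the interaction tests below address. The largest rises included hspb9, a small heat shock gene, at 4.36 (SE 0.46), tcap, the titin cap protein of the muscle Z-disc, at 4.31 (SE 0.41), pth1a, a parathyroid hormone, at 3.93 (SE 0.59), hspb11 at 3.32 (SE 0.41) and ankrd1a, a stretch-responsive ankyrin repeat gene, at 3.10 (SE 0.49), with edgeR adjusted p of 8.20e-09, 7.66e-10, 6.02e-06, 2.60e-07 and 3.01e-05. The sixth was bmb (2.66). Skeletal muscle genes as a list did not pass (median -0.03, camera adjusted p = 0.456). The mean of tcap was 91.8 ± 69.7 CPM in mutants (n = 7) against 4.70 ± 1.72 CPM in wild types (n = 9), and single mutants differed widely, from 7.79 to 186.0 CPM. The largest falls were the lens crystallins crygm2d11 (-3.84), crygm2d15 (-3.54) and crygm2d16 (-2.28), the cone transducin gene gnb3a (-2.90), ampd1, the muscle AMP deaminase (-2.48), and igfn1.3 (-2.31).

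**Figure D3:**
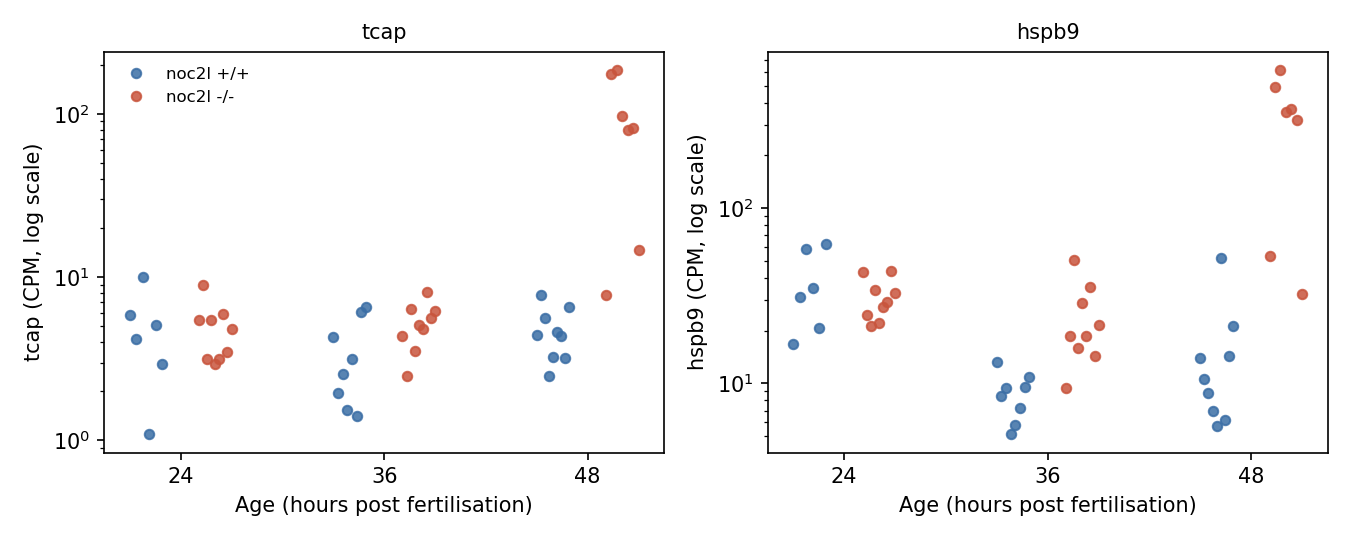
Levels of tcap (left) and hspb9 (right) in CPM on a log scale for each embryo (points) by age in hours post fertilisation, wild types in blue and mutants in red. At 48 hpf tcap ran from 7.79 to 186.0 CPM among the 7 mutants.

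Genes of ribosome assembly were higher at 48 hpf too. Of 124 factors 50 were higher and none lower (85 and 0 adjusted over the list alone), with a median of 0.50 (camera adjusted p = 2.52e-51, adjusted p = 0.000177 with an estimated correlation); sdad1 (0.94), rrp12 (0.86), npm1a (0.85), gar1 (0.63) and dkc1 (0.61) rose, whereas noc3l (0.33) and fcf1 (0.41) did not pass. RNA polymerase I and III genes had 4 of 28 members higher (13 adjusted over the list alone) and a median of 0.39 (camera adjusted p = 6.04e-07, adjusted p = 0.00109 with an estimated correlation), with polr1d at 0.68. Among 68 translation factors and tRNA synthetases 10 were higher and 1 lower (20 and 1 adjusted over the list alone), for example eif3c (0.78), eif2b2 (0.65), eif5b (0.62) and farsa (0.59), with a median of 0.20 (camera adjusted p = 1.19e-09, adjusted p = 0.0205 with an estimated correlation). Cytosolic ribosomal proteins had 2 of 77 members higher, rpl11 (0.46) and rpl19 (0.33), with 2 higher and 1 lower adjusted over the list alone; rpl10a read -0.36. With 6 embryos per group rpl19 lost its call (edgeR adjusted p = 0.0848). The median of the list was 0.14 (camera adjusted p = 2.59e-07, adjusted p = 0.729 with an estimated correlation). In wild types the mean log2 CPM of the ribosome biogenesis list fell with age, so younger embryos read higher. It ran from 4.662 to 5.188 at 24 hpf, 4.273 to 4.651 at 36 hpf and 4.108 to 4.295 at 48 hpf. Mutants read 4.646 to 4.981 at 36 hpf and 4.517 to 4.798 at 48 hpf. At 48 hpf mutant embryos 1 to 5 lay above every wild type at 36 hpf, and embryos 6 and 7 did not. How much of these rises a developmental delay covers was not tested.

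The arrest and cell death list at 48 hpf had 7 of 29 members higher and none lower (12 and 0 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 1.3e-11, adjusted p = 0.00104 with an estimated correlation). The values were 2.61 for rps27l, 1.65 for ccng1, 1.41 for mdm2 and 0.68 for baxa, all called; cdkn1a (1.87, SE 0.96) and bbc3 (0.74, SE 0.31) had edgeR adjusted p of 0.459 and 0.293, and passed with limma voom (limma adjusted p = 0.0141 and 0.0493).

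Lens, yolk and liver transcripts were lower at 48 hpf. Of 46 lens crystallins 18 were lower and none higher (26 lower and 1 higher adjusted over the list alone), with a median of -0.95 (camera adjusted p = 5.41e-25, adjusted p = 0.0205 with an estimated correlation); crygm2d20 read -2.06 and crygm2d18 -1.50. Crystallin paralogs are near-identical, so values of single members are uncertain. Among 32 yolk syncytial and lipoprotein genes 8 were lower (15 adjusted over the list alone), including apoa4a (-2.05) and apoa4b.2 (-1.23), which encode apolipoproteins, mt2, a metallothionein (-1.86), and afp4 (-0.86), with a median of -0.29 (camera adjusted p = 6.84e-15, adjusted p = 0.00119 with an estimated correlation). Liver genes had 2 of 33 members lower, apom at -1.51 and a2ml at -0.58, named after their values were seen, and a median of -0.21 (camera adjusted p = 6.04e-07, adjusted p = 0.00607 with an estimated correlation). At this age alas2 was also lower (-0.71), in a list of erythroid genes that did not pass (median 0.10, camera adjusted p = 0.963).

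Several further lists passed at 48 hpf on the preset correlation and not on the estimated one. Heat shock genes had 3 of 24 members higher, hspb9, hspb11 and the collagen chaperone serpinh1b (0.61, named after its value was seen), with a median of 0.23 (adjusted p = 0.123 with an estimated correlation). Retina genes had a median of -0.21, differentiated neurons -0.15, mitochondrially encoded transcripts -0.14 and the 5 lymphoid and thymus genes -0.36, while notochord and floor plate genes had 0.18 and mRNA splicing genes 0.08. With an estimated correlation the camera adjusted p of these 6 lists were 0.123, 0.318, 0.358, 0.0794, 0.0604 and 0.529. The other 18 lists passed the set test at no age (lowest camera adjusted p 0.0613, medians between -0.18 and 0.27). They were apoptosis machinery outside the arrest and cell death list, the integrated and endoplasmic reticulum stress response, interferon response, p63, p73 and DNA repair, haematopoietic progenitors, myeloid cells, endothelium, inner ear and lateral line, heart, pigment cells and neural crest, cartilage and pharyngeal arches, hatching gland, exocrine pancreas, endocrine pancreas, intestine, kidney, circadian clock, and nuclear-encoded oxidative phosphorylation. The stress response list split at 48 hpf, with 5 members higher and 5 lower. With the age score as a covariate crygm2d18 read -0.46 (edgeR adjusted p = 0.283). Calls of mt2, gnb3a, dkc1, polr1d and farsa were also lost, at values of -1.29, -2.22, 0.43, 0.54 and 0.50 (edgeR adjusted p of 0.16, 0.0742, 0.082, 0.074 and 0.0929). The score itself differed between genotypes at this age, and crystallins were not left out of it. Losses under this covariate may therefore follow in part by construction. With limma voom 627 genes were called at 48 hpf, and with only the 48 hpf libraries 634.

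**Figure D4:**
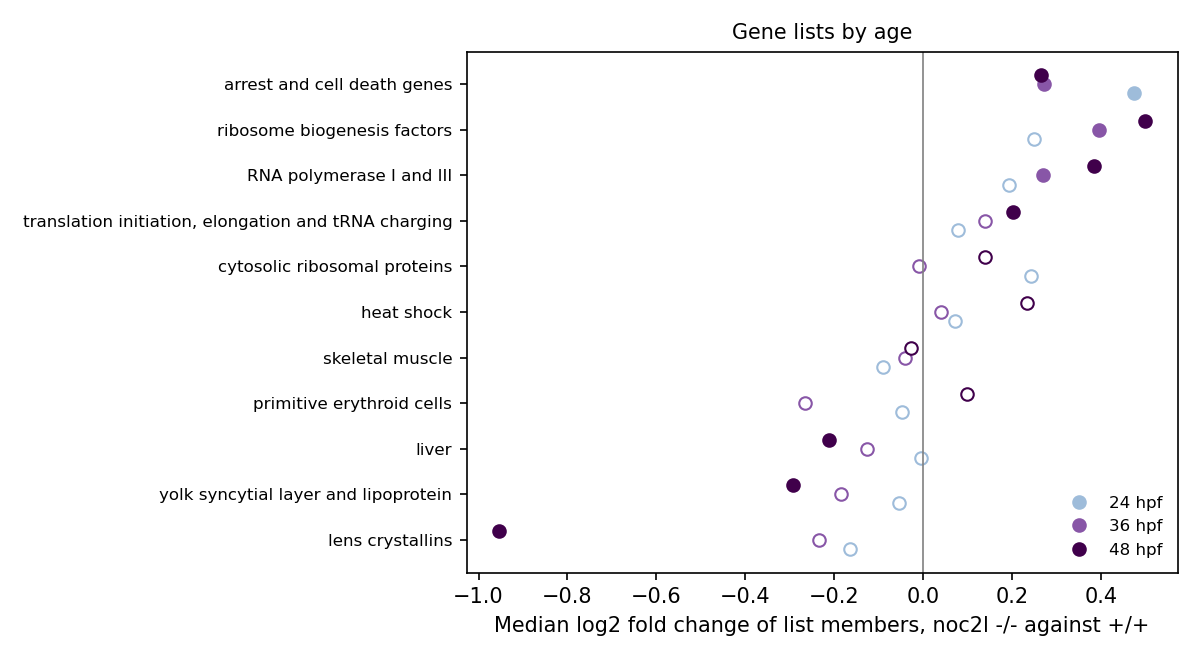
Median log2 fold change of mutants against wild types (horizontal axis) for 11 gene lists at 24, 36 and 48 hours post fertilisation (point colour); filled points passed the camera test with an estimated correlation at an adjusted p of 0.05, open points did not. Ribosome biogenesis factors lay at 0.25, 0.40 and 0.50, and lens crystallins at -0.95 at 48 hpf.

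Genes called at different ages overlapped in the same direction. For rises, 16 genes were shared by 24 and 36 hpf, 67 by 36 and 48 hpf and 12 by 24 and 48 hpf, where independent lists would share 0.111, 1.51 and 0.268 (one-sided Fisher's exact test, p = 1.81e-34, 1.36e-100 and 1.58e-18). For falls 1, 11 and 1 were shared (p = 0.00183, 1.97e-21 and 0.0142, Fisher's exact test). No library served 2 ages, but all calls shared 1 filter and 1 spread per gene. A gene of low spread is more easily called at every age, so independent lists are an imperfect reference. In total 403 genes were called at some age and 13 at all 3, noc2l, mdm2, ccng1, rps27l, isg20, SH3TC1 and lyrm1 among them; lyrm1 was named after its values were seen.

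Whether the genotype effect itself differed between ages was tested as an interaction. Between 36 and 24 hpf no gene passed with edgeR or with any other tool run (DESeq2 0, limma voom 0), and 943 genes had an unadjusted p under 0.05. Between 48 and 36 hpf 9 genes passed, 5 with a positive and 4 with a negative difference: the effect changed by 4.25 for pth1a, 3.76 for tcap, 3.08 for hspb11 and 2.57 for flnca, filamin C, a muscle cross-linker, and by -3.25 for crygm2d11, -2.92 for crygm2d15 and -1.06 for sb:cb37. For both crystallins the fall was deeper at 48 hpf. Between 48 and 24 hpf 10 genes passed, 7 with a positive and 3 with a negative difference, among them hspb9 (4.66), tcap (4.37), hspb11 (3.04), flnca (2.57), igfn1.3 (-2.59) and sb:cb37 (-1.52). The smallest adjusted p of both belonged to the embryonic globin hbbe3, named after its values were seen, at 1.47 and 1.21 (edgeR adjusted p = 4.6e-09 and 8.93e-06). Of the differences named by the rule, only those of sb:cb37 and hspb9 passed with limma voom (limma adjusted p of 0.0687 to 0.812 for the others). That of pth1a also failed with DESeq2, with only the libraries compared and with the replicate block (edgeR adjusted p = 0.0774 and 0.103 for the last 2). Outside limma voom hspb11 was also lost with only the libraries compared (edgeR adjusted p = 0.0586 and 0.0816) and, for 48 against 24 hpf, with the replicate block (edgeR adjusted p = 0.0916). The difference of crygm2d15 was lost with only the libraries compared, thinning and the age score (edgeR adjusted p = 0.0801, 0.278 and 0.0926), and that of sb:cb37 between 48 and 36 hpf with thinning (edgeR adjusted p = 0.0623). No arrest or cell death gene named here passed an interaction test.

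Changes with age framed these effects. In wild types 1392 genes were called between 24 and 36 hpf (814 higher, 578 lower) and 2384 between 36 and 48 hpf (1112 higher, 1272 lower). Early rises were led by cox4i1l (3.72) and the crystallins crygm2d2, crygm2d8 and crygm2d4 (3.61, 3.32 and 3.19), and falls by pcdh8 (-2.81), chrng, the embryonic acetylcholine receptor subunit (-2.38), per1b, a clock gene (-2.33), and ctsc (-2.27). Between 36 and 48 hpf ampd1 (5.12), ifitm5 (5.01), crygm2d11 (4.89) and crygm2d15 (4.84) rose most, and mapk12b (-2.63), ctslb (-2.04), the embryonic globin hbbe3 (-1.99) and the hatching enzyme he1.2 (-1.99) fell most. Ages 12 h apart fall at opposite times of day, so age and time of day were not separable in these steps for genes such as per1b, which read 18.7, 3.74 and 10.0 CPM in wild types at 24, 36 and 48 hpf.

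In mutants 1818 genes were called between 24 and 36 hpf (1001 higher, 817 lower) and 1645 between 36 and 48 hpf (780 higher, 865 lower). The largest rises from 24 to 36 hpf were crygm2d4 (3.35), crygm2d18 (3.17), crygm2d8 (3.07) and crygm2d1 (2.97), and the largest falls tbx6 (-4.07) and msgn1 (-3.60), markers of unsegmented mesoderm of the tail, with the urate pathway genes uox (-3.39) and urahb (-3.38). From 36 to 48 hpf tcap (4.16), s100a10a (3.80), hspb9 (3.76) and hspb11 (3.13) rose most. In the same step egln3 (-2.49), apoa4a (-2.33), rbp4l (-2.11) and dao.1 (-2.03) fell most. With limma voom dao.1 lost its call (limma adjusted p = 0.0922), as did cox4i1l in wild types from 24 to 36 hpf (limma adjusted p = 0.0591).

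The position of each embryo on the wild-type course of development was then scored. Mutants at 48 hpf corresponded to wild types of 44.3 ± 1.74 hpf (n = 7), against 47.7 ± 1.3 hpf for wild types scored the same way (n = 9), a score difference of -0.617 (exact permutation test, p = 0.000874, adjusted p = 0.00262). At 24 hpf the equivalent ages were 23.8 ± 1.63 (n = 9) and 25.1 ± 1.93 (n = 6; exact permutation test, p = 0.142), and at 36 hpf 34.2 ± 2.44 (n = 9) and 35.9 ± 2.37 (n = 8; exact permutation test, p = 0.167). Without the genes called for genotype at 48 hpf the difference there was -0.278 (exact permutation test, p = 0.062). With 50 genes each way the 24 hpf difference was -0.326 (exact permutation test, p = 0.0122). Across genes, which are not independent replicates, the genotype effect at 48 hpf correlated at -0.12 (Pearson) and -0.121 (Spearman) with the wild-type change from 24 to 36 hpf, with 45.3% of genes of the same sign. Over the 362 called genes these were -0.519, -0.488 and 21.3%. To share no library, the effect at 24 hpf was set against the wild-type change from 36 to 48 hpf (-0.0166 and -0.0356 over all genes) and that at 36 hpf against the change from 24 to 48 hpf (-0.099 and -0.123). Over called genes these were 0.109, 0.0451 and 60% of the same sign for 20 genes at 24 hpf, and -0.236, 0.0548 and 30.2% for 116 genes at 36 hpf.

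**Figure D5:**
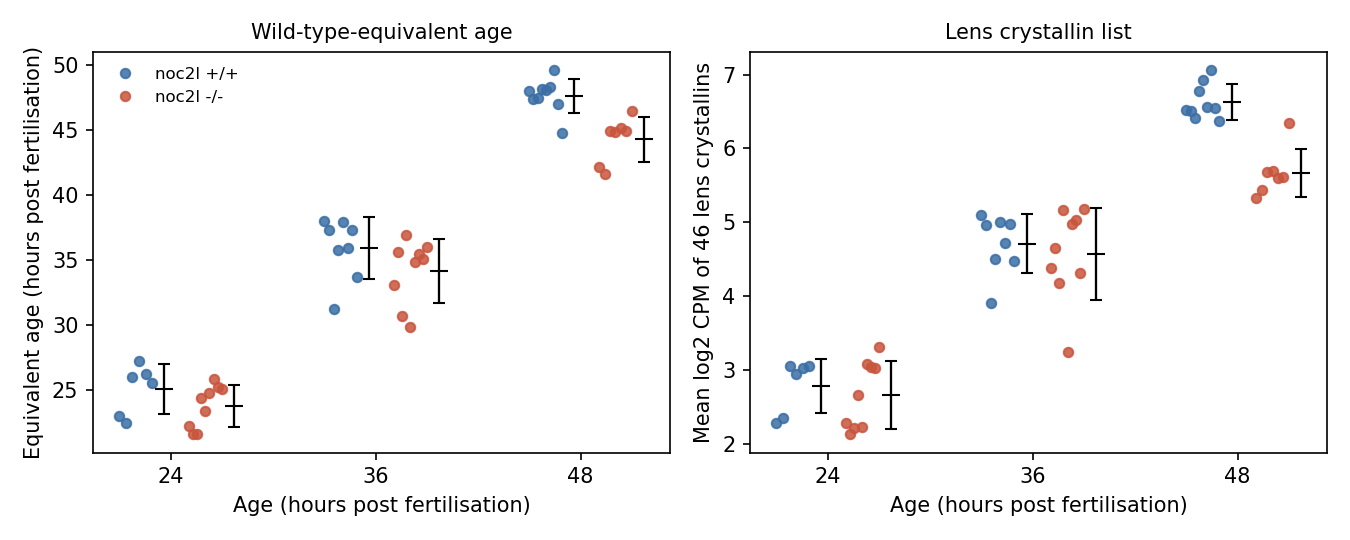
Wild-type-equivalent age in hours post fertilisation (left) and mean log2 CPM of the 46 lens crystallins (right) for each embryo (points) by age, wild types in blue and mutants in red, with the group mean and SD in black. At 48 hpf the mutant mean lay at 44.3 hpf against 47.7 hpf in wild types.

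Homozygous mutants share the chromosome segment around noc2l, so linked genes were counted apart, with chromosomes from GRCz12tu. At 36 hpf 13 of 480 linked genes were called (2.71%) against 87 of 13264 elsewhere (0.656%), an odds ratio of 4.22 (Fisher's exact test, p = 4.34e-05). At 48 hpf 15 of 480 were called against 314 of 13264 (odds ratio 1.33, Fisher's exact test, p = 0.285), and at 24 hpf 2 against 10 (odds ratio 5.54, p = 0.0637, Fisher's exact test). Within 10 Mb of noc2l the 24 hpf odds ratio was 11.8 (Fisher's exact test, p = 0.0166).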

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

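The tests of explanations for single patterns below were chosen after the results were seen; the counts over other splits of the libraries were planned, except that of genes shared with 36 hpf. Whether a random division of the embryos could give such counts was examined with 100 splits per comparison, the real one included. For the genotype comparisons labels were permuted within every age at once, with 1 fit over all 48 libraries. At 24 hpf 6 splits gave at least the 20 genes called, the highest 110, so that count does not exclude chance. A split calling 110 genes points to a structure among the 24 hpf embryos. Wild-type embryos 1 and 2 and mutant embryos 1, 2, 3 and 5 had the lowest equivalent ages there (21.6 to 23.4 hpf). Their lens list means were also the lowest, 2.135 to 2.358 log2 CPM against 2.664 to 3.316 in the others. Whether that split separated them was not tested, and the list tests at 24 hpf were not adjusted for equivalent age. The real split called 16 of the genes higher at 36 hpf, and 1 of the 100 splits, the real one, reached this (highest other 0). Permuted labels mix mutants and wild types at 36 hpf too, which widens the spread of those same genes in the shared fit. They are then harder to call at 24 hpf in any other split, so this count cannot exclude chance. At 36 hpf only the real split reached 116 genes (highest other 1), and at 48 hpf only the real split reached 362 (highest other 25). The same widening can lower the counts of the other splits at 36 and 48 hpf. For the effect difference between 48 and 36 hpf 1 split, the real one, reached 9 genes (highest other 4). For that between 48 and 24 hpf 2 reached 10 (highest other 11). Between 36 and 24 hpf, with 0 genes called, all 100 did (highest other 3). Permuting within every age removed the genotype effect at all ages, not only its difference between them. The counts for effect differences therefore cannot tell such a difference from an effect equal at both ages. For the changes with age only the real split reached the counts, 1392 and 2384 in wild types (highest others 146 and 294) and 1818 and 1645 in mutants (3 and 1).

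Outlying libraries were sought in 54 groups of values that share libraries, where chance flags about 1 in 20. Neither an excess over chance nor a cause was tested. By the gap to the nearest other library 6 libraries stood apart. They were mutant embryo 2 at 36 hpf (total of 9.07 in units of 1000000 counts, the highest), mutant embryo 4 at 48 hpf (17554 genes detected, the lowest), mutant embryo 5 at 36 hpf (18.6% of counts in 10 genes, the highest), mutant embryo 5 at 24 hpf (noc2l at 16.2 CPM, the highest), mutant embryo 7 at 48 hpf (rps27l at 324 CPM, the lowest) and wild-type embryo 1 at 24 hpf (rps27l at 128 CPM, the highest).

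Effects that differed between ages by the interaction test were as follows. The differences between 48 and 36 hpf were 4.25 for pth1a, 3.76 for tcap, 3.08 for hspb11 and 2.57 for flnca, and -3.25, -2.92 and -1.06 for crygm2d11, crygm2d15 and sb:cb37. Those between 48 and 24 hpf were 4.66 for hspb9, 4.37 for tcap, 3.04 for hspb11, 2.57 for flnca, -2.59 for igfn1.3 and -1.52 for sb:cb37.

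Of the 6 largest rises at 48 hpf, tcap, hspb9, hspb11, ankrd1a and pth1a were lowest in mutant embryos 1 and 7, whereas bmb was more even (8.06 to 18.2 CPM): for embryos 1 to 7 tcap read 7.79, 175.4, 186.0, 97.2, 79.4, 82.3 and 14.7 CPM, and hspb9 53.4, 492, 617, 353, 370.2, 319.6 and 32.3 CPM. Developmental delay is argued against for the group of 6, since the median log2 ratio of the mutant mean to the highest wild-type group mean at any age was 2.31. For the mutants as a group a heat shock at collection is also argued against. The genes hsp70.2, hsp70.3 and hsp70l had a median log2 change of 0.624, far below hspb9 and hspb11. Single embryos were not compared for these hsp70 genes. A response that differs between mutant embryos may remain, as a hypothesis with no further test, and different handling of single embryos stays open.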

How the results depend on the processing

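The noc2l level kept its direction and call under every alternative run (log2 between -2.26 and -1.37), and 175 of 201 alternatives of the main results stayed on the same side of the threshold, within 1.5 times the count or, for same-sign shares, within the 95% binomial interval. Leaving out wild-type embryo 4 or mutant embryo 5 at 24 hpf, and the age score as a covariate, were chosen after seeing the data. The covariate was not applied to changes with age, and the thinned fit left out the 3 shallow libraries. The cause was not tested unless stated.

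The replicate numbers name single embryos and do not pair them: deviations of same-numbered wild types and mutants correlated at 0.017, 0.0083 and 0.017 on average at the 3 ages. With the replicate block 16, 104 and 354 genes were called at 24, 36 and 48 hpf, and 0, 10 and 12 for the effect differences of 36 and 24, 48 and 36, and 48 and 24 hpf; with age 1212 and 2335 were called in wild types and 1778 and 1552 in mutants.

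DESeq2 called 46 genes at 24 hpf, 14 for 48 against 36 hpf and 43 for 48 against 24 hpf. Limma voom called 5 at 24 hpf, 176 at 36 hpf, 627 at 48 hpf, and 4 and 4 for those differences. With only the libraries compared 8 genes were called at 24 hpf and 634 at 48 hpf, and with 6 embryos per group, fewer samples, 64 at 36 hpf. For 48 against 24 hpf the stricter filter called 17, dropping shallow libraries 21, thinning 17 and the age score as covariate 30; dropping wild-type embryo 4 gave 16 and dropping mutant embryo 5 gave 13. At 48 hpf 334 genes were called with that covariate, 200 of them among the 362. At an adjusted p under 0.01, a stricter threshold, shared rises were 9, 39 and 7 for 24 with 36, 36 with 48 and 24 with 48 hpf, and shared falls of 36 with 48 hpf were 6.

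Among genes of mean log2 CPM over 5 the same-sign shares were 46.9%, 44.4% and 42.1% at 24, 36 and 48 hpf. The age score at 24 hpf passed with 50 genes each way (-0.326), and at 48 hpf did not without called genes (-0.278), where score genes were removed by construction. Linked genes at 24 hpf passed within 10 Mb (odds ratio 11.8). For single named genes 1472 of 1546 comparisons kept their call, 68 lost it, 6 gained it and 0 changed sign. Of 37 set-test calls 12 held with an estimated correlation. Another scaling moved the median of all genes by at most 0.0309 (log2).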

Other observations

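The test of correlation in this part was chosen after the values were seen. Stress-response genes divided at 48 hpf: atf3 (1.83), atf5b (0.93), cebpb (0.84), atf4b (0.71) and atf4a (0.56), transcription factors of the integrated stress response, were higher, and the endoplasmic reticulum chaperones hsp90b1 (-0.84), hspa5 (-0.79), sdf2l1 (-0.55), pdia4 (-0.54) and manf (-0.52) were lower, all called by edgeR and named after their values were seen. At 36 hpf atf4b (0.67) and atf4a (0.42) were called, and hspa5 read -0.33.

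Levels of arrest and cell death genes were uneven among mutants at 24 hpf: for embryos 1 to 9 ccng1 read 915, 578, 529, 1815, 537, 1855, 997, 1775 and 1768 CPM, against 399 to 593 CPM in wild types. The equivalent ages of the same embryos were 22.3, 21.6, 21.6, 24.4, 23.4, 24.8, 25.9, 25.2 and 25.1 hpf. Among the mutants these values fall into separate clusters, so no correlation is given. Wild-type embryos 1 to 6 lay at 22.98, 22.44, 26.01, 27.27, 26.27 and 25.55 hpf, so uneven age was not particular to mutants. Wild types labelled as mutants do not account for the set: of the 5 mutants with the lowest mean of the arrest and cell death list, 1 (embryo 5) had noc2l in the range of the deep wild types, and for that embryo a wrong label stays open. A candidate explanation is that activation follows the developmental age of the embryo. Among the 9 mutants at 36 hpf the mean of the arrest and cell death list gave Spearman's rho of 0.667 with equivalent age (exact permutation p = 0.0589, adjusted p = 0.0883 over 3 relations). Pearson's r was 0.441 (exact permutation p = 0.23), and 0.92 without the 2 embryos farthest from the median age. The same omission gave -0.65 in mutants at 48 hpf and 0.0971 in wild types at 36 hpf. In the 7 mutants at 48 hpf rho was -0.786 (exact permutation p = 0.048, adjusted p = 0.0883), and in the 8 wild types at 36 hpf 0.143 (exact permutation p = 0.752), so the relation is not settled.

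Lens crystallin and yolk transcripts were lower in mutants at 48 hpf, which developmental delay could give. For the yolk list it is argued against, because in 7 of 7 mutants its mean lay below every wild-type library at 36 and 48 hpf. For the lens list the equivalent age was 42 ± 2.02 hpf, against 44.8 ± 1.75 hpf by score genes outside the list (n = 7), a mean difference of -2.81 hours (SD 1.42), lower in 7 of 7 embryos (exact sign-flip permutation p = 0.0156). As a group the mutants thus read younger by the lens list than by the other score genes. That difference also met the criterion set for delay, under 2 SD between embryos. That SD is the spread of single embryos, not the uncertainty of the mean, so the criterion says little. In embryo 7 the ages were 46.21 and 46.65 hpf, and wild types were not compared in this way. Whether a delay of the whole embryo covers the fall of the lens list therefore stays open. Movement of reads between near-identical crystallins is argued against too: the summed level of all 46 was 7120 ± 1800 CPM in mutants (n = 7) against 14400 ± 2540 CPM in wild types (n = 9; exact permutation p = 0.000175).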
